A study of Homo sapiens with 6 samples.

How the data were processed

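Total RNA of MDA-MB-231 cells, an established human triple-negative breast cancer line, was measured on 6 Illumina BeadChip arrays. The labels give 3 groups of 2 arrays: mock-transfected control cells, cells that stably over-expressed a tRNA-Glu gene (anticodon TTC), and cells that stably over-expressed a tRNA-Arg gene (anticodon CCG). Nothing in the labels says that the 2 arrays of a group came from separate cultures. The p-values then measure only the spread between these arrays, which may be technical.

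Per the file headers, the authors deposited non-normalized bead summary values as intensity on a linear scale, with a detection p-value for each of 47323 probes on each array. The authors also deposited a table of processed intensity values for the same arrays. Its quantiles were alike on all 6 arrays, with medians between 39.6 and 39.7, and its ranks within each array were those of the non-normalized values. The submitters' processing notes name lumi, with no version and no settings. A final table deposited by the authors holds a log2-like fold change per gene symbol for each over-expression line, with no values per array and no p-values. The sign of those fold changes and their exact scale are not stated, and they ran opposite to over-expression minus control in the array values. The direction of every difference given here comes from the array labels, over-expression minus control or tRNA-Glu minus tRNA-Arg.

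The non-normalized intensities were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values, an offset of 16 and quantile normalization, and were taken to log2. Probes were kept with a detection p under 0.01 on at least 2 of the 6 arrays, which left 18106 probes. Of all probes on the array, 30113 had 1 named gene, 8 had several and 17202 had none in the annotation table used. Gene symbols were checked through the Entrez identifiers of a RefSeq gene table, used only for names. Of the kept probes, 14337 had 1 named gene. The probe with the highest mean over all arrays stood for its gene, which gave 10877 genes, of which 2855 had several kept probes.

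Differences were tested with limma (lmFit and eBayes) in 1 fit over the 3 groups, with 3 residual degrees of freedom and 4.28 prior degrees of freedom. Benjamini-Hochberg adjustment covered all genes of a comparison, and a gene was called at an adjusted p under 0.05. A probe with a detection p of 0.05 or more on both arrays of a group was treated as not above background there. Its fold is then given as a lower bound, against the mean of the lowest signals above background or of the probe's own signals where those were higher.

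Before the data were examined, 38 gene lists were fixed, and 36 of them had at least 5 measured members. After the files were read, 11 older list symbols were matched to current ones by name alone. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. No list was called in any comparison with the estimated correlation. This also held for lists whose estimate lay below the preset, such as mitochondrial ribosomal proteins (-0.010) and oxidative phosphorylation (-0.013). A higher correlation therefore does not account for the loss of those calls. With the correlation estimated, camera takes its p-values from the 3 residual degrees of freedom of the fit, so this test has little power here. Its adjusted p-values do not show that a list was unchanged. Counts of list members called are also given adjusted over the list alone. The named genes follow a rule that was also fixed before the data were examined. In each comparison it takes the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups. It adds up to 4 members of smallest unadjusted p per described list, the genes EXOSC2 and GRIPAP1 that the study is known for, and the synthetases EPRS1 and RARS1.

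The fit and the list test were tested on simulated data with 200 changed genes among 10877. In the simulated tRNA-Glu comparison with control, 95% of genes changed 2-fold were recovered, 66% of those changed 1.5-fold and 0% of those changed 1.2-fold. In the simulated tRNA-Arg comparison with control these shares were 98%, 64% and 0%, and 9.09% of the calls were false. In the simulated comparison between the lines they were 98%, 76% and 0%. False calls made up 5.19% of calls in the tRNA-Glu simulation and 4.90% in that between the lines. Each share comes from 1 simulated data set. In the measured data far more genes were called, 59.5% and 47.2% in the tRNA-Glu and tRNA-Arg lines and 42.6% between them. The adjustment then allows smaller differences to pass, so the simulated shares do not carry over to the measured data.

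The number of arrays limits the precision. The arrays detected between 16650 and 17704 probes at a detection p under 0.01. Alternatives covered the background correction, the normalization, the authors' processed values, the filter, the choice of probe, the arrays in the fit, the variance model, array weights, the replicate number as a block, a 1.5-fold minimum, and each array left out in turn. Median scaling aligned the arrays on the median of all 47323 probes. On each array the median signal (43.8 to 46.2) lay below the lowest signal above background (47.6 to 50.7). This setting thus aligned values near background and not the brightness of the detected genes. Tests of codon content were planned and not run, because no coding sequences were at hand. Without the filter on detection, list members that had failed it also enter. A list's median is then taken over more genes, so it does not show a change in the measured members. A slide block was not run, because the files used here name no slides. The authors' final table could not serve as an alternative, since it holds no values per array. Figures were drawn with matplotlib 3.10.9.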

Results

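Gene expression was measured in MDA-MB-231 cells that stably over-expressed tRNA-Glu or tRNA-Arg and in mock-transfected control cells, with 2 arrays per group. The comparisons ask which mRNAs differ in abundance when either tRNA is over-expressed. Mean non-normalized intensities per array ranged from 250.6 to 331.3, and medians from 43.8 to 46.2. The 2 arrays of a group correlated across genes with r between 0.996 and 0.997, and arrays of different groups with r between 0.958 and 0.984. Genes are not independent replicates, so these values only describe the arrays. The first principal component held 67.6% of the variance and parted control from both lines, and the next held 23.6% and parted the lines.

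In the tRNA-Glu line, genes of mitosis were higher than in control, and targets of the amino acid response and genes of DNA replication were lower. PLK1, a mitotic kinase, was 7.88-fold higher (log2 difference 2.98 ± 0.08 SE, n = 2 arrays per group, limma adjusted p = 3.75e-06). These directions oppose the authors' deposited table, whose fold change for PLK1 in this line is -1.81. XPOT, the export receptor of tRNAs, was 4.86-fold lower (log2 difference -2.28 ± 0.08 SE, adjusted p = 5.11e-06). In all, 3451 genes rose and 3023 fell among 10877 tested, and 4403 were not called. Of these, 1477 rose and 1380 fell by at least 1.5-fold. With median scaling 2198 genes were called higher and 1668 lower. The arrays of the groups did not overlap for 80.2% of genes, where chance gives 33.3%.

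Of the 53 measured mitosis genes, 45 rose and 3 fell in the tRNA-Glu line, with the same counts adjusted over the list alone and a median log2 difference of 1.07 (camera adjusted p = 2.70e-13). The list was not called with the estimated correlation (adjusted p = 0.167 with an estimated correlation). KIF20A, a mitotic kinesin, was 6.78-fold higher, AURKA, a spindle kinase, 6.28-fold, and CDC20, an activator of the anaphase-promoting complex, 5.16-fold. Histone genes also rose, 15 of 21 measured and 16 adjusted over the list alone, with none falling and a median of 0.58 (adjusted p = 0.0011; adjusted p = 0.167 with an estimated correlation). H2AC20 was 2.48-fold higher. Histone genes share closely similar sequences, so their probes are uncertain. The median of the histone list was 0.10 without the filter on detection, which adds members beyond the 21 measured of 65 fixed. It was 0.38 without background correction.

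DNA replication genes fell, 27 of 54 measured against 6 that rose, with the same counts adjusted over the list alone and a median of -0.23 (adjusted p = 0.0027; adjusted p = 0.167 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was 2.97-fold lower. MCM6, part of the replicative helicase, was 1.97-fold lower, and PCNA, the sliding clamp, 1.81-fold. With median scaling the median of this list was -0.13. Targets of ATF4 and the amino acid response fell, 20 of 32 against 6 that rose, with 20 and 7 adjusted over the list alone and a median of -0.64 (adjusted p = 0.0011; adjusted p = 0.213 with an estimated correlation). ASNS, asparagine synthetase, was 3.73-fold lower, PSAT1, of serine synthesis, 3.74-fold, and CTH, of cysteine synthesis, 3.16-fold.

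Inflammatory and interferon genes were higher in the tRNA-Glu line. Among NF-kB targets and cytokines, 19 of 30 rose and 5 fell, with the same counts adjusted over the list alone and a median of 0.59 (adjusted p = 0.0028; adjusted p = 0.167 with an estimated correlation). SAA1, an acute-phase protein, was 6.41-fold higher, LCN2, an iron-carrier protein, 5.93-fold, and IL11 5.56-fold, with 5.77-fold in the tRNA-Arg line. Without the filter on detection the median of this list was 0.37, and with the mean of its probes SAA1 differed by 1.73 on the log2 scale. Among interferon-stimulated genes, 27 of 48 rose and 8 fell, with 28 and 8 adjusted over the list alone and a median of 0.29 (adjusted p = 0.0070; adjusted p = 0.167 with an estimated correlation). OASL was 5.74-fold higher, IFIT1 5.64-fold and ISG15 4.83-fold. IFIT3 was 4.20-fold higher, with another of its probes of opposite sign and a log2 difference of 0.94 with the mean of its probes. The blood cell markers LAPTM5 and CD68 were 2.78-fold and 2.25-fold higher in the same arrays, and CSF1R was higher by 1.32 on the log2 scale. Of the 6 measured blood cell markers, 4 rose and 1 fell, with the same counts adjusted over the list alone, and the list was not called (median of 0.80, adjusted p = 0.152; adjusted p = 0.385 with an estimated correlation). It was called under 4 other settings, with median scaling (0.84), with all probes tested (0.88) and without control replicate 1 (1.23) or 2 (1.13), while its median was 0.05 without the filter on detection and 1.199 without tRNA-Glu replicate 1.

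Proteases and invasion genes rose, 18 of 30 against 3 that fell, with 18 and 4 adjusted over the list alone and a median of 0.45 (adjusted p = 0.0070; adjusted p = 0.252 with an estimated correlation). MMP1, a collagenase, was 3.62-fold higher and ID1 4.16-fold, while ADAM10 was 1.86-fold lower. Without the filter on detection this median was 0.23. Collagens and matrix proteins rose, 18 of 31 against 4, with the same counts adjusted over the list alone and a median of 0.45 (adjusted p = 0.0079; adjusted p = 0.252 with an estimated correlation). COL8A1 was 3.01-fold higher and COL1A1 2.26-fold. Without the filter on detection this median was 0.23. Epithelial adhesion genes and luminal keratins rose, 9 of 13 against 1, with the same counts adjusted over the list alone and a median of 0.62 (adjusted p = 0.016; adjusted p = 0.328 with an estimated correlation). KRT8 was 3.07-fold and KRT19 2.85-fold higher. Without the filter on detection, which adds members beyond the 13 measured of 34 fixed, the median of this list was 0.03. Both keratins are also on the list of luminal breast cell markers, of which 6 of 12 rose and 3 fell, with the same counts adjusted over the list alone. That list was not called (median of 0.42, adjusted p = 0.577; 0.17 without the filter on detection, 0.09 with probes detected on all arrays and -0.01 with all probes tested).

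Mitochondrial ribosomal proteins rose in the tRNA-Glu line, 41 of 75 against 6 that fell, with the same counts adjusted over the list alone and a median of 0.28 (adjusted p = 0.0028; adjusted p = 0.167 with an estimated correlation). MRPL41 was 2.46-fold higher. Oxidative phosphorylation genes rose, 36 of 70 against 8, with the same counts adjusted over the list alone and a median of 0.27 (adjusted p = 0.0032; adjusted p = 0.167 with an estimated correlation). ATP5ME, of the ATP synthase, was 1.93-fold higher, while SDHD, of complex II, was 1.86-fold lower. With median scaling the median of this list was 0.46. RNA polymerase III transcripts rose, 9 of 12 against 1, with the same counts adjusted over the list alone and a median of 0.61 (adjusted p = 0.037; adjusted p = 0.521 with an estimated correlation). RPPH1, the RNA of RNase P, was 6.23-fold higher. The estimated correlation of this list was 0.32, far above the preset 0.01. The call of this list was lost with cyclic loess (median 0.58), without control replicate 2 (0.47) and without tRNA-Glu replicate 2 (0.50).

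Outside these lists, MSMP, a secreted microseminoprotein, was not above background in the tRNA-Glu line and at least 37.0-fold lower than in control (adjusted p = 6.71e-07). ASS1, of arginine synthesis, was 5.21-fold lower and GABPA 3.95-fold. GOLM2 was 4.65-fold lower. EDIL3 was not above background in the line and at least 3.75-fold lower, and REEP3 was above background on 1 of the 2 tRNA-Glu arrays. CABYR, a calcium-binding sperm protein, was 8.89-fold higher. TH, tyrosine hydroxylase, was not above background in control and at least 7.08-fold higher. SPANXC, SPANXD, SPANXB1 and SPANXA2, testis antigens, were between 7.46-fold and 8.32-fold higher. These near-identical gene copies cannot be told apart with certainty by probe.

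In the tRNA-Arg line, mitosis genes were again higher than in control, and DNA replication and ATF4 targets lower. KIF20A was 7.32-fold higher (log2 difference 2.87 ± 0.08 SE, n = 2 arrays per group, limma adjusted p = 5.56e-06). CST1, a secreted cysteine protease inhibitor, was 11.8-fold lower (log2 difference -3.56 ± 0.10 SE, adjusted p = 5.56e-06). In all, 2478 genes rose and 2659 fell, and 5740 of the 10877 tested were not called. Of these, 910 rose and 869 fell by at least 1.5-fold. The share of rises among the calls was 48.2%, and 58.6% with median scaling, which called 1342 higher and 949 lower. The arrays did not overlap for 74.6% of genes, where chance gives 33.3%.

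Of the 53 mitosis genes, 50 rose and 0 fell in the tRNA-Arg line, or 51 and 0 adjusted over the list alone, with a median of 1.19 (adjusted p = 7.55e-25; adjusted p = 0.107 with an estimated correlation). PLK1 was 6.92-fold higher, AURKA 6.40-fold and CENPE, a centromere kinesin, 4.76-fold. Histone genes rose, 14 of 21 with none falling, with the same counts adjusted over the list alone and a median of 0.69 (adjusted p = 1.10e-05; adjusted p = 0.160 with an estimated correlation). Without the filter on detection this median was 0.09. DNA replication genes fell, 25 of 54 against 2 that rose, with the same counts adjusted over the list alone and a median of -0.22 (adjusted p = 0.0025; adjusted p = 0.160 with an estimated correlation). E2F2 was 2.29-fold lower and MCM6 2.00-fold. With median scaling this list was not called (median -0.12).

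ATF4 targets fell, 21 of 32 against 5 that rose, with 22 and 5 adjusted over the list alone and a median of -0.50 (adjusted p = 7.20e-04; adjusted p = 0.219 with an estimated correlation). ASNS was 2.84-fold lower, PCK2 2.45-fold and TRIB3 1.97-fold. SLC1A4 was above background on 1 of the 2 tRNA-Arg arrays. Mitochondrial ribosomal proteins rose, 38 of 75 against 4, with 41 and 5 adjusted over the list alone and a median of 0.27 (adjusted p = 1.10e-05; adjusted p = 0.134 with an estimated correlation). MRPS15 was 1.73-fold higher. MRPL35 was 2.23-fold higher, with another of its probes of opposite sign and a log2 difference of 0.34 with the mean of its probes. Oxidative phosphorylation genes rose, 32 of 70 against 4, with the same counts adjusted over the list alone and a median of 0.20 (adjusted p = 0.0013; adjusted p = 0.160 with an estimated correlation). NDUFA7 was 1.66-fold higher, while CYCS, cytochrome c, was 1.76-fold lower. With median scaling the median of this list was 0.32.

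Proteasome genes rose, 14 of 34 against 4, with the same counts adjusted over the list alone and a median of 0.19 (adjusted p = 0.0074; adjusted p = 0.209 with an estimated correlation). PSMB2 was 1.76-fold higher. With median scaling the median of this list was 0.36. NRF2 targets rose, 12 of 22 against 2, with the same counts adjusted over the list alone and a median of 0.25 (adjusted p = 0.0079; adjusted p = 0.212 with an estimated correlation). AKR1C2 was 2.31-fold higher and TXNRD1, thioredoxin reductase, 1.69-fold (log2 difference 0.48 with the mean of its probes), while ABCC3, a transporter, was 5.04-fold lower. With median scaling this list was not called (median 0.36). YAP and TEAD targets rose, 10 of 21 with none falling, with the same counts adjusted over the list alone and a median of 0.17 (adjusted p = 0.0087; adjusted p = 0.304 with an estimated correlation). IGFBP3 was 1.95-fold and CCN2 1.64-fold higher. With median scaling the median of this list was 0.32.

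Collagens and matrix proteins rose in the tRNA-Arg line, 15 of 31 against 7, or 18 and 7 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.035; adjusted p = 0.315 with an estimated correlation). COL6A3 was 2.01-fold higher, while LAMB2 was 1.98-fold lower. The call was lost with probes detected on all arrays (median 0.30), without control replicate 2 (0.27) and without tRNA-Arg replicate 2 (0.32), and without the filter on detection the median was 0.18. Proteases and invasion genes rose, 11 of 30 against 5, with the same counts adjusted over the list alone and a median of 0.17 (adjusted p = 0.035; adjusted p = 0.315 with an estimated correlation). PLAT, tissue plasminogen activator, was 2.86-fold higher and ADAMTS1 2.36-fold. The call was lost without control replicate 1 (median 0.15) and without tRNA-Arg replicate 2 (0.17), and without the filter on detection the median was 0.09.

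Of the lists called in the tRNA-Glu line, 4 did not pass in the tRNA-Arg line, and of these only the NF-kB and interferon lists differed between the lines. Among NF-kB targets and cytokines, 14 of 30 rose and 7 fell, with the same counts adjusted over the list alone and a median of 0.11 (adjusted p = 0.231; 0.17 with median scaling and 0.07 without the filter on detection). IL11 was 5.77-fold higher and not called between the lines (adjusted p = 0.703). Among interferon-stimulated genes, 18 of 48 rose and 14 fell, or 19 and 15 adjusted over the list alone, with a median of -0.01 (adjusted p = 0.435; -0.03 to 0.07 under other settings). OASL was 3.95-fold and IFIT1 3.19-fold higher. Epithelial adhesion genes and luminal keratins had 7 of 13 rising and 0 falling, or 7 and 1 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.055; adjusted p = 0.315 with an estimated correlation). This list was called under 12 other settings (medians of 0.22 to 0.28) but not with the estimated correlation, and had a median of 0.03, not called, without the filter on detection. RNA polymerase III transcripts had 6 of 12 rising and 1 falling, or 6 and 2 adjusted over the list alone, with a median of 0.20 (adjusted p = 0.222; 0.06 to 0.33 under other settings). Between the lines the epithelial list had a median of 0.31 (adjusted p = 0.379; 0.02 without the filter on detection, 0.09 with all probes tested and 0.10 with probes detected on all arrays) and the RNA polymerase III transcripts of 0.22 (adjusted p = 0.338).

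Of the lists called in the tRNA-Arg line, 3 did not pass in the tRNA-Glu line, and of these only YAP and TEAD targets differed between the lines. Proteasome genes had 17 of 34 rising and 7 falling and a median of 0.21 (adjusted p = 0.183; 0.08 to 0.36 under other settings). NRF2 targets had 11 of 22 rising and 4 falling and a median of 0.25 (adjusted p = 0.513; 0.01 without the filter on detection and 0.14 with the mean of a gene's probes). YAP and TEAD targets had 6 of 21 rising and 5 falling and a median of 0.02 (adjusted p = 0.904). The counts of these 3 lists were the same adjusted over the list alone. Between the lines the proteasome list had a median of 0.03 (adjusted p = 0.518; -0.01 to 0.06 under other settings) and the NRF2 list of -0.19 (adjusted p = 0.338; -0.12 without the filter on detection and -0.11 without tRNA-Arg replicate 2).

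MSMP was not above background in the tRNA-Arg line either and at least 37.8-fold lower than in control. PADI4, of protein citrullination, was 7.12-fold lower, ASS1 6.93-fold, KLRC2 6.02-fold and HTRA1, a secreted protease, 5.52-fold. CST4 was above background on 1 of the 2 tRNA-Arg arrays. CABYR was 9.26-fold higher, and the 4 SPANX genes between 5.96-fold and 7.10-fold.

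**Figure D1:**
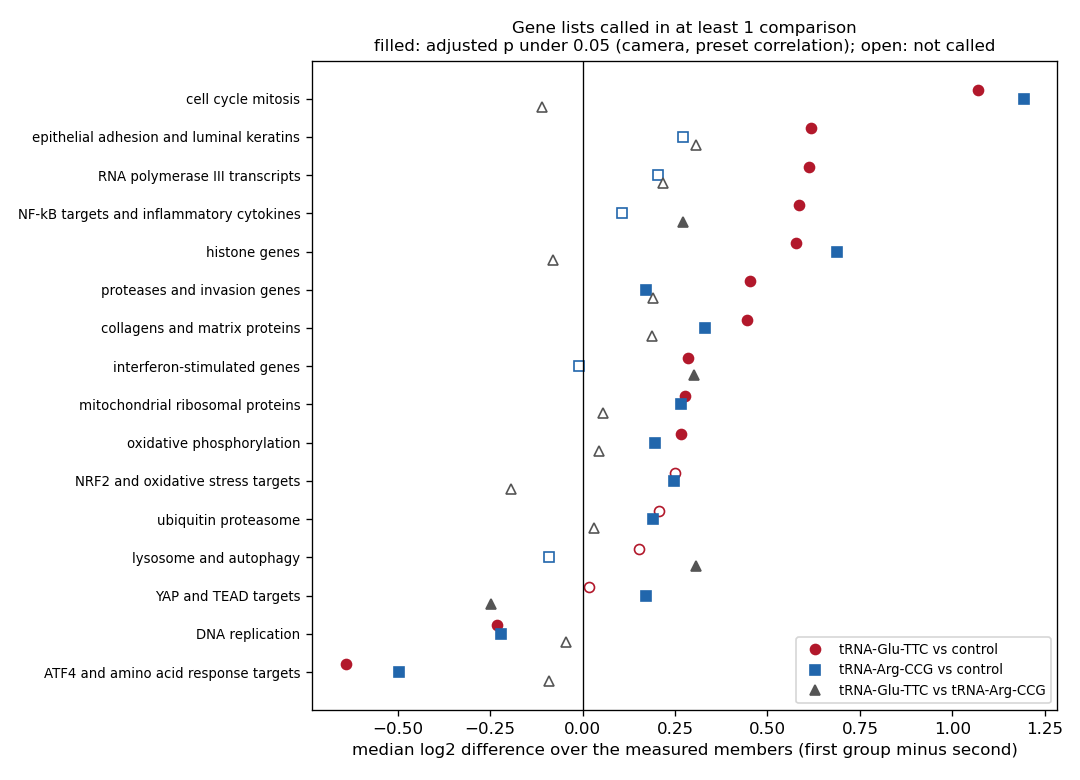
Median log2 difference over the measured members of each gene list called in at least 1 comparison, with filled symbols for lists called by camera at the preset correlation and open symbols for the others. The mitosis list lies at 1.07 and 1.19 in the comparisons with control and at -0.11 between the lines.

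Both lines changed many genes alike relative to the shared control arrays. In the same direction, 1911 genes rose and 1791 fell in both, where independent lists would share 786.2 and 739. Another 131 were called in opposite directions. Of the 3702 genes called alike, 1425 also differed between the lines. With median scaling 1602 genes were called alike. The log2 differences of the lines correlated across genes with r = 0.77, against 0.50 in 100 simulations of unchanged groups with the same controls. The covariance was 0.21, against a simulated 0.0082. The simulation used only the spread between arrays of a group. A deviation common to both control arrays is not in it, so it cannot bound the part due to the shared controls. The 2 control arrays cannot be split into 2 sets of 2, so part of the overlap may come from the shared controls.

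**Figure D2:**
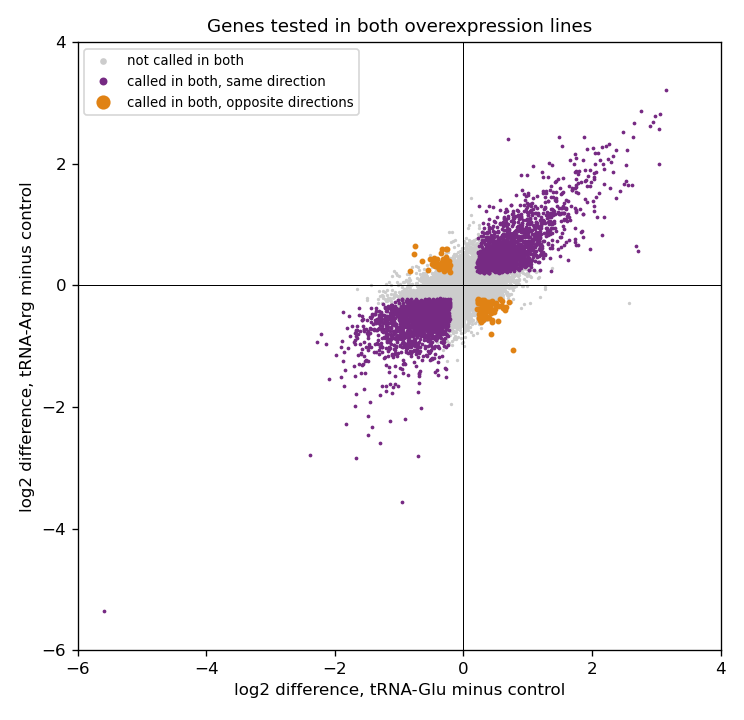
Log2 difference from control of each tested gene in the tRNA-Glu line (horizontal axis) and the tRNA-Arg line (vertical axis), coloured by whether it was called in both. The 3702 genes called alike lie along the diagonal, and the 131 called in opposite directions lie in the other quadrants.

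Between the lines, interferon-stimulated, inflammatory and lysosomal genes were higher in the tRNA-Glu line, and YAP and TEAD targets were higher in the tRNA-Arg line. LCN2 was 7.22-fold higher in the tRNA-Glu line (log2 difference 2.85 ± 0.14 SE, n = 2 arrays per group, limma adjusted p = 3.67e-04). XPOT was 2.55-fold lower there (log2 difference -1.35 ± 0.08 SE, adjusted p = 5.54e-04). In all, 2648 genes were higher and 1982 lower in the tRNA-Glu line, and 6247 of 10877 were not called. The share of higher genes among the calls was 57.2%, and 42.0% with median scaling, which called 559 higher and 772 lower. The arrays did not overlap for 74.1% of genes, where chance gives 33.3%.

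Of 48 interferon-stimulated genes, 25 were higher and 2 lower in the tRNA-Glu than in the tRNA-Arg line, or 25 and 3 adjusted over the list alone, with a median of 0.30 (adjusted p = 2.99e-04; adjusted p = 0.433 with an estimated correlation). IFIT1 was 1.77-fold higher, BST2 1.75-fold and HLA-F 1.55-fold. IFIT3 was 1.92-fold higher, with another of its probes of opposite sign. With the mean of a gene's probes the log2 differences were 0.33 for IFIT3 and 0.36 for HLA-F. The blood cell markers LAPTM5, CD14 and CD68 were 1.83-fold, 1.84-fold and 1.36-fold higher in the same arrays. Of 6 such markers 3 were higher and 0 lower, or 3 and 1 adjusted over the list alone, and the list was not called (median of 0.38, adjusted p = 0.133) but was called with all probes tested and without control replicate 1 or 2 (medians of 0.44, 0.44 and 0.45), with a median of 0.08 without the filter on detection. The CD68 call between the lines was lost with median scaling (0.49). Lysosome and autophagy genes were higher, 22 of 36 against 3, with the same counts adjusted over the list alone and a median of 0.31 (adjusted p = 0.0013; adjusted p = 0.433 with an estimated correlation). The cathepsins CTSD, CTSF and CTSB were 1.98-fold, 1.78-fold and 1.52-fold higher. They fell in the tRNA-Arg line (log2 differences from control of -1.24, -0.87 and -0.59) and were not called in the tRNA-Glu line (-0.25, -0.04 and 0.01). In the tRNA-Glu line CTSD was called under 8 other settings (-0.24 to -0.35) and differed by -0.16 without control replicate 2. In the tRNA-Arg line the CTSB call was lost with median scaling (-0.41), and with the mean of its probes CTSB differed by -0.90. Against control the lysosome list was not called. In the tRNA-Glu line 14 of 36 rose and 6 fell (median of 0.15, adjusted p = 0.231; 0.03 to 0.25 under other settings), and in the tRNA-Arg line 7 rose and 13 fell (median of -0.09, adjusted p = 0.471; 0.01 with median scaling), with the same counts adjusted over the list alone. The luminal breast cell markers were higher for 7 of 12 and lower for 2, or 9 and 2 adjusted over the list alone, in the same arrays. Their list was not called (median of 0.46, adjusted p = 0.133; 0.30 without background correction and 0.24 without the filter on detection).

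NF-kB targets and cytokines were higher in the tRNA-Glu than in the tRNA-Arg line, 17 of 30 against 2, or 18 and 2 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0028; adjusted p = 0.433 with an estimated correlation). SAA2 was 4.43-fold, SAA1 4.08-fold and CSF3 2.32-fold higher, and with the mean of its probes SAA1 differed by 1.30 on the log2 scale. The call was lost with probes detected on all arrays (median 0.24). YAP and TEAD targets were lower, 10 of 21 against 2, or 11 and 2 adjusted over the list alone, with a median of -0.25 (adjusted p = 0.0028; adjusted p = 0.433 with an estimated correlation). CRIM1 was 2.34-fold, TGFB2 1.95-fold, CCN2 1.88-fold and F3, tissue factor, 1.84-fold lower.

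Other genes with large differences were CST1, 6.07-fold higher in the tRNA-Glu line, SERPINA3 (3.56-fold), EBI3 (3.35-fold) and MUC1 (2.60-fold). CST4 was also higher and above background on 1 of the 2 tRNA-Arg arrays, so no fold is given. FLG, filaggrin, was 3.27-fold lower in the tRNA-Glu line, GNG12 3.02-fold, NEK7 2.71-fold, TWF1 2.70-fold, GOLM2 2.69-fold, LBR 2.66-fold and RBM24 2.49-fold. With the mean of its probes LBR differed by -0.80 on the log2 scale.

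EXOSC2, a subunit of the RNA exosome, differed from control by -0.23 ± 0.08 SE in the tRNA-Glu line (log2, limma adjusted p = 0.044) and by 0.09 ± 0.08 SE in the tRNA-Arg line (adjusted p = 0.381). Between the lines the difference was -0.32 ± 0.08 SE (adjusted p = 0.018). GRIPAP1, an endosomal protein, differed from control by 0.31 ± 0.10 SE in the tRNA-Glu line (adjusted p = 0.026) and by -0.25 ± 0.10 SE in the tRNA-Arg line (adjusted p = 0.069). Between the lines it was higher in the tRNA-Glu line by 0.55 ± 0.10 SE (adjusted p = 0.0047). In the authors' deposited table, EXOSC2 has 0.20 and GRIPAP1 -0.02 for the tRNA-Glu line, again of opposite sign. In the tRNA-Glu line the EXOSC2 call was lost under 10 other settings. The difference stayed at -0.23 in 6 of them, namely without the filter on detection, with all probes tested, with only the 4 arrays compared, with the replicate number as a block and without either tRNA-Arg array. It was -0.15 with median scaling, -0.20 and -0.26 without control replicate 1 or 2, and -0.17 without tRNA-Glu replicate 2. The GRIPAP1 call there was lost under 4 settings, with median scaling (0.32), with the mean of its probes (0.18) and without control replicate 1 (0.23) or tRNA-Glu replicate 2 (0.25). Between the lines the EXOSC2 call was lost with median scaling (-0.34) and without tRNA-Arg replicate 1 (-0.35), tRNA-Arg replicate 2 (-0.29) or tRNA-Glu replicate 2 (-0.26), and the GRIPAP1 call with median scaling (0.53). In the tRNA-Arg line GRIPAP1 gained the call under 3 settings, without background correction (-0.22), when detected on all arrays (-0.25) and with a trend and robust variance (-0.25). With the mean of its probes GRIPAP1 differed by 0.36 between the lines, and EXOSC2 differed by 0.19 from control in the tRNA-Arg line with median scaling.

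**Figure D3:**
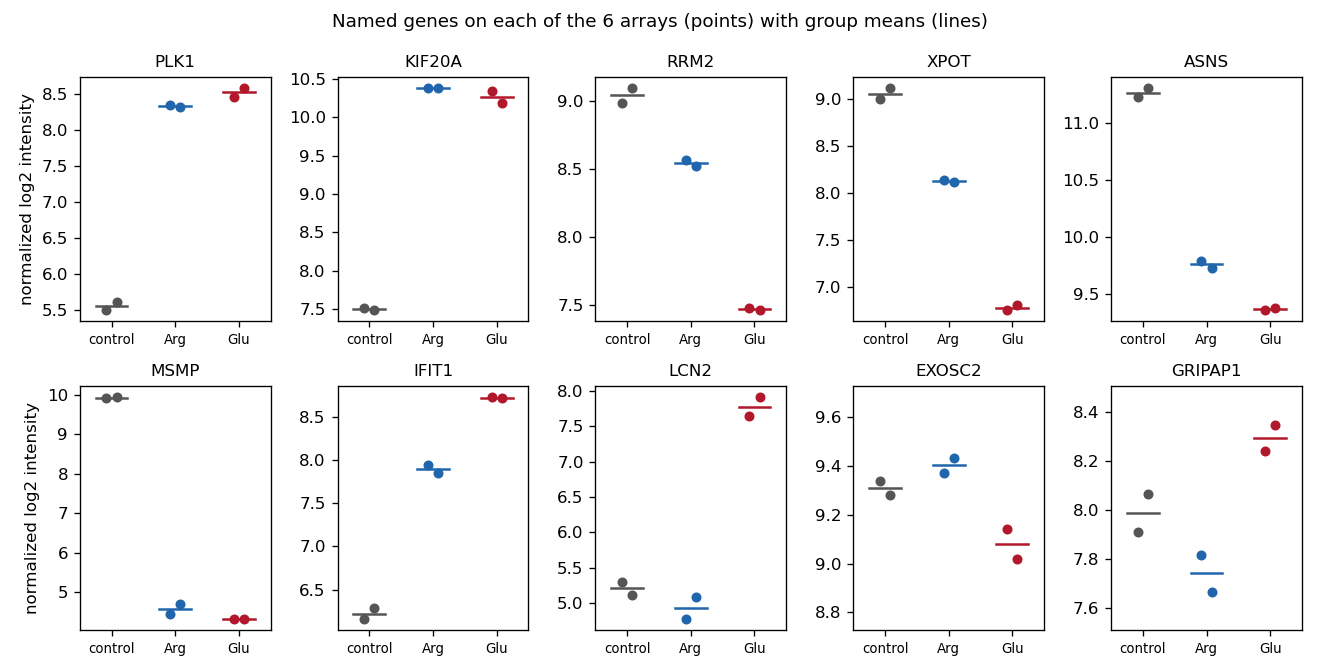
Normalized log2 intensity of 10 named genes on each array (points) with the mean of each group (lines), for control, tRNA-Arg and tRNA-Glu cells, each panel with its own vertical scale. EXOSC2 lies at 9.31, 9.40 and 9.08 and PLK1 at 5.55, 8.34 and 8.53 in these groups.

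EPRS1, which charges tRNA-Glu, fell in both lines, with a difference of -0.50 ± 0.09 SE in the tRNA-Glu line (log2, adjusted p = 0.0021) and of -0.36 ± 0.09 SE in the tRNA-Arg line (adjusted p = 0.012). With median scaling neither call held (-0.29 and -0.16), and the call in the tRNA-Arg line was also lost without control replicate 2 (-0.29) and without tRNA-Arg replicate 1 (-0.32). RARS1, which charges tRNA-Arg, differed by 0.09 ± 0.07 SE (adjusted p = 0.319) and 0.17 ± 0.07 SE (adjusted p = 0.089), the latter called with a trend and robust variance (0.17), and by 0.35 and 0.36, not called, with median scaling. The cytosolic aminoacyl-tRNA synthetases were not called as a list in the tRNA-Glu line (adjusted p = 0.141), although 10 of 19 fell and 4 rose, with the same counts adjusted over the list alone. IARS1 was 1.98-fold and MARS1 1.73-fold lower, and HARS1 was 1.53-fold higher. In the tRNA-Arg line 9 of 19 fell and 0 rose, with the same counts adjusted over the list alone (list adjusted p = 0.103), and the list was called without the filter on detection and with all probes tested (medians of -0.22). The medians of the synthetases with median scaling were -0.19 in the tRNA-Glu line and -0.05 in the tRNA-Arg line, not called.

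The tRNA modification and processing enzymes were not called as a list against control (adjusted p = 0.456 and 0.401). Of 46 measured, 21 rose and 11 fell in the tRNA-Glu line, and 14 rose and 10 fell in the tRNA-Arg line, with the same counts adjusted over the list alone. TRNT1, which adds the CCA end of tRNAs, was 2.53-fold lower in the tRNA-Glu line and 1.87-fold in the tRNA-Arg line. POP1, of RNase P, was 1.78-fold and 1.64-fold higher, and POP5, of the same enzyme, 1.94-fold higher in the tRNA-Glu line. The RNA exosome and its cofactors were not called either (adjusted p = 0.825 and 0.512). Of 19 measured, 7 rose and 6 fell in the tRNA-Glu line, and 4 rose and 3 fell in the tRNA-Arg line, with the same counts adjusted over the list alone. DIS3, an exosome nuclease, was 2.18-fold and 1.63-fold lower, and DIS3L, a related nuclease, 1.46-fold and 1.59-fold higher.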

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

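Of the tests in this part, the one on DNA replication genes was chosen only after the result was seen. The code of the tests on blood cells and on exchanged labels was corrected after a first output, which left their outcomes as they were. The shift from S phase was first taken to fit and was left open once the histone genes were included. The other scalings of the phase genes were also chosen after seeing the data.

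Probes without 1 named gene stayed out of the comparisons, and some of them also differed from control. Of 3769 such probes kept, 847 were higher and 777 lower in the tRNA-Glu line, and 623 were higher and 558 lower in the tRNA-Arg line (limma, adjusted p under 0.05 with all kept probes in the fit).

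Mitosis genes were higher in both lines than in control. A single array as the source is argued against, since the lowest median of the list over both lines with any 1 array left out was 1.03. With a larger share of dividing cells, S-phase and mitotic genes were taken to rise alike. The DNA replication list did not rise, with a median of -0.22 or lower in both lines. Histone genes, also of S phase, did rise (medians of 0.58 and 0.69). The fall of the DNA replication list was known before this test was written, so the test could not fail and does not decide the question. With median scaling the mean of the DNA replication list in the tRNA-Arg line went from -0.23 ± 0.04 to -0.13 ± 0.04 SE across genes and its call was lost, with a smaller difference and a spread of 0.16 between arrays instead of 0.01. A shift of cells from S phase towards G2 and mitosis remains open. The G1/S genes outside the fixed lists had medians of -0.51 and -0.32 (from -0.54 to -0.28 under 4 other scalings). The 30 G2/M genes had 0.68 and 0.82, while the histone genes went the other way. Without the filter on detection, which adds histone genes beyond the 21 measured, the histone medians were 0.10 and 0.09. Closely similar sequences make these probes uncertain.

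Interferon-stimulated genes were higher in the tRNA-Glu than in the tRNA-Arg line. The lowest median with any 1 array left out was 0.31, which argues against a single array. Of 4 genes abundant in blood cells, 3 were not detected on both tRNA-Glu arrays, which argues against blood cells as the source. The remaining one, LAPTM5, was detected on both, with a mean log2 intensity of 9.64 against 8.77 in the tRNA-Arg line, and CD68, outside these 4, had 11.46 against 11.02. The over-expressed tRNA, a response to stable transfection and differences between the lines that arose by selection remain open.

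The authors' deposited fold changes ran opposite to over-expression minus control, for 98.5% of the 5443 called genes found in that table in the tRNA-Glu line and 98.9% of 4311 in the tRNA-Arg line. No assignment of the 3 group names to the arrays gave a correlation above 0.9 in both columns, and the best gave 0.51, which argues against exchanged labels. Columns that subtract the over-expression line from control were considered only after the correlations had been seen, and no test apart from the pattern itself was found. The lower correlation of the 2 columns with control minus over-expression was 0.92 with the authors' processed values and 0.898 with the background-corrected values used in the comparisons, which restates the opposite direction. This explanation therefore stays open, and the direction of the deposited columns remains unstated.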

How the results depend on the processing

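The alternatives were fixed before the data were examined, except 4 other scalings of the cell cycle phase genes, which were chosen after seeing the data. Over 60 list results, 1067 of 1137 values kept test direction and side of the threshold, 38 lost the call, 22 gained it and 10 changed test direction. Over 222 gene results, by the sign of the difference, these numbers were 3885, 57, 12 and 2 of 3956 values. Of these results, 24 lists and 31 genes were added after their main values were known. Of the 38 list calls lost, 27 were lost with the estimated correlation, under which no list kept its call. The values kept include uncalled results that stayed uncalled. They also include settings that left out an array of a group not compared. The test direction of a list is camera's and can differ from the sign of its median. The uncalled exosome list in the tRNA-Glu line had medians of -0.04 and, with median scaling, 0.09, and counts as kept. So do the uncalled luminal markers there, with 0.42 and, with all probes tested, -0.01. In the tRNA-Glu line against control CTSB, not called, changed direction with the mean of its probes (-0.21), and CTSF without tRNA-Glu replicate 2 (0.024; -0.0998 without replicate 1), causes untested. The list of cytosolic synthetases between the lines, which was not called, changed its test direction with median scaling (median -0.012), and the cause was not tested. The uncalled cytosolic ribosomal proteins changed test direction in the tRNA-Glu line, where the main median was 0.005. This happened with median scaling (0.21), all probes tested (0.017) and the mean of a gene's probes (0.018). In the tRNA-Arg line their test direction changed with cyclic loess (-0.025), also untested. The uncalled YAP and TEAD targets in the tRNA-Glu line changed test direction with median scaling (0.043), without the filter on detection (0.034), with all probes tested and the mean of a gene's probes (both 0.019) and without tRNA-Glu replicate 1 (0.041), and had a median of -0.038 without control replicate 1, cause untested. Requiring a 1.5-fold change left 1477 genes higher and 1380 lower in the tRNA-Glu line, 910 and 869 in the tRNA-Arg line, 552 and 580 between the lines and 1190 in both lines, by its construction. Median scaling gave 2198 and 1668, 1342 and 949, 559 and 772, and 1602 in both lines. It aligned the arrays near background level. The spread of the DNA replication list between arrays then went from 0.01 to 0.21 in the tRNA-Glu line. In the tRNA-Arg line it went from 0.01 to 0.16. How far this wider spread accounts for the counts was not tested. Testing all kept probes gave 4888 lower in the tRNA-Glu line and 3220 lower between the lines, with more probes tested, and 9 lists between the lines. Without the filter on detection 7 lists were called between the lines, and the cause was not tested. With an estimated correlation, and so only 3 degrees of freedom in the list test, 0 lists were called in each of the 3 comparisons, against 12, 11 and 4.

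With 1 array left out, its group's remaining array is assumed to vary like the others. Counts then ranged from 2710 to 3390 higher and 2468 to 2976 lower in the tRNA-Glu line, from 1803 to 2325 and 1957 to 2555 in the tRNA-Arg line, and from 1411 to 2664 and 1190 to 1960 between the lines, with 2824 to 3235 in both lines. Lists called ranged from 11 to 13, 9 to 12 and 4 to 6. Between the lines the counts were 1703 higher and 1318 lower without tRNA-Arg replicate 1, 1704 and 1304 without tRNA-Arg replicate 2, and 1411 and 1190 without tRNA-Glu replicate 2, with fewer arrays.

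Arrays of the same replicate number did not deviate together (correlations of 0.02, -0.03 and -0.05), so the numbers do not pair them. With the replicate number as a block, 3400 genes were higher and 2951 lower in the tRNA-Glu line, 2359 and 2525 in the tRNA-Arg line, and 2520 and 1899 between the lines. Codon content tests, a slide block and the authors' final table as values per array were not run. Folds are given as bounds where a gene was above background on neither array of a group, and left out where on 1 of 2.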

Other observations

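The 131 genes called in opposite directions were seen after their values were known. SERPINA3, an acute-phase protease inhibitor, was 0.77 above control on the log2 scale in the tRNA-Glu line (limma adjusted p = 3.46e-04) and -1.07 in the tRNA-Arg line (adjusted p = 1.52e-04). LBR, the lamin B receptor, had -0.75 and 0.65, and LGR4, a Wnt pathway receptor, -0.78 and 0.52. NNMT, nicotinamide N-methyltransferase, had 0.43 and -0.80, and IFI27, an interferon-stimulated gene, 0.65 and -0.41. The IFI27 call in the tRNA-Arg line was lost under 6 other settings (-0.24 to -0.41), the NNMT call in the tRNA-Glu line under 3 (0.25 to 0.42) and the LGR4 call in the tRNA-Arg line with median scaling (0.51). Without background correction SERPINA3 and NNMT had -0.69 and -0.52 in the tRNA-Arg line and LGR4 -0.49 in the tRNA-Glu line. With the mean of its probes LBR had -0.29 in the tRNA-Glu line.

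Some of the lists described here were not called. Of 67 measured cytosolic ribosomal proteins, 6 rose and 8 fell in the tRNA-Glu line, or 5 and 6 adjusted over the list alone (list adjusted p = 0.606). In the tRNA-Arg line 7 rose and 10 fell, or 4 and 7 adjusted over the list alone (adjusted p = 0.906). Of 40 hypoxia and glycolysis genes, 8 rose and 18 fell in the tRNA-Glu line, or 10 and 18 adjusted over the list alone, and 5 rose and 18 fell in the tRNA-Arg line, with the same counts adjusted over the list alone. The medians were -0.12 and -0.14 (adjusted p = 0.139 and 0.076), and the list was called in the tRNA-Arg line without the filter on detection (-0.09). There the median was -0.0005 without control replicate 2, -0.21 without tRNA-Arg replicate 2, -0.06 with probes detected on all arrays and -0.03 with median scaling, which gave -0.07 in the tRNA-Glu line. Among splicing factors with RS domains, 17 of 36 fell and 7 rose in the tRNA-Glu line, with the same counts adjusted over the list alone (list adjusted p = 0.139). Of 23 blood cell markers on the array, 11 were detected on no array and 4 on all 6.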
